A study of Homo sapiens with 4 samples.

How the data were processed

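The series holds eCLIP libraries from T-47D cells that express Flag-tagged APOBEC3B after doxycycline induction: 2 immunoprecipitated libraries and 2 size-matched input libraries. Groups and replicate numbers were taken from the sample titles. Per the labels, the replicates are biological repeats, the cassette also carries an HA-tagged uracil glycosylase inhibitor behind a P2A peptide, the molecule is poly(A) RNA, the pull-down used an anti-Flag antibody and libraries followed the ENCODE eCLIP protocol. A list was analysed for each immunoprecipitated library, matched to its replicate by the name of the sheet it came from. Lists for the input libraries were not analysed here.

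Each deposited list has no header and gives a chromosome, a start, an end, a score and a strand for each called stretch of crosslink positions. The sheet names give PureCLIP as the caller, and the submitters' processing notes give the build GRCh38. The unit is the authors' score, one value per stretch, in the deposited files, not scaled between lists, and it was used only to rank, split or shorten a list. For stretches of 3 nt whose score had more than 6 decimals, 742 of 782 scores in IP 1 and 2828 of 2990 in IP 2 became a number of at most 6 decimals (tolerance 5e-08) when multiplied by 3, against 119 and 401 when multiplied by 4, which is what a mean over the positions of a stretch would give. The aligner, the adapter and duplicate steps, the version and parameters of PureCLIP, any threshold on the score and any use of the input libraries in calling are not given in the sources used here. Replicates were called separately, 1 list per library. A called position needs enough crosslinked ends over its surroundings, so abundant RNAs, long transcripts and deeper libraries give more calls. The depth of the libraries is unknown; the length of each list is all that stands for it.

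Stretches on the same strand at most 8 nt apart were merged into a binding region, and its position was the centre of its highest scoring stretch. IP 1 gave 8562 regions (226 with more than 1 stretch) and IP 2 gave 33768 (1133 with more than 1 stretch), with scores up to 229 and 218. Genes came from a RefSeq table of the same build with 59702 placed genes, which was used for spans and classes. Where genes overlap, a region went to a small RNA first, then to a protein coding gene, a lncRNA, another class and a pseudogene, and within a class to the shortest gene. Regions on contigs outside the assembled chromosomes, 22 in IP 1 and 84 in IP 2, were given no gene. Protein coding genes that overlap another one held 19.4% of regions in each list, and their assignment is uncertain.

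A genome sequence, exons and gene strands were not used here. The planned tests of the crosslinked nucleotide, of UC motifs, of enriched k-mers, of RNA structure, of repeats, of position along the mRNA and of exon, intron, UTR and antisense classes were therefore not run, and the class test was reduced to inside or outside a gene. For the same reason the plan was changed in 3 ways: positions were redrawn within the gene and not within a feature class, gene lists were matched on genomic span in place of exon length, and gene direction was taken from the strand of the regions. The list tests were run two-sided.

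The overlap of the lists was set against 200 redraws of the positions within their genes (one-sided). Regions outside genes were redrawn within 10 kb. Distances to gene ends were set against 200 redraws within the gene (two-sided, 1000 nt), for protein coding and lncRNA genes. Shares have Wilson 95% intervals, which cover counting error only, and shares of the lists were compared with Fisher's exact test, adjusted by Benjamini-Hochberg over 9 shares. Means are over 2 lists with the SD. Each of 20 gene lists was set against 10000 random lists matched gene by gene on class and on 10 equal classes of genomic span within that class, with Benjamini-Hochberg adjustment over the 20 lists, and a list was called when the adjusted p was under 0.05 in both libraries in the same direction. With 2 libraries of one group, p-values describe these lists, and no test compares conditions.

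The lists were cytosolic ribosomal proteins, translation factors, replication-dependent histones, spliceosomal snRNAs, snoRNAs and scaRNAs, other small structured RNAs, snoRNA host genes, nuclear lncRNAs, mitochondrial transcripts, hnRNP genes, SR proteins and splicing regulators, luminal and estrogen response genes, heat shock and chaperone genes, cytoskeleton and glycolysis genes, interferon and double-stranded RNA response genes, DNA damage and replication genes, the APOBEC family, and markers of fibroblasts, of basal epithelium and of blood cells. The genes named in the text follow a rule: APOBEC3B, the 20 genes with the most regions over both lists, up to 4 members of each list, the genes of the 10 highest scoring regions found in both lists, and any gene with at least 1% of a list's regions, 75 genes in all, some of which are not reported here. Others are named as members of a fixed list, as overlapping genes or, in the closing section, as chosen after their values were seen. The groups, gene lists and naming rule were set before the data were examined, as were the other settings to be tried, apart from those said in the text to have been chosen or added after the data were seen.

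The overlap step was tested on simulated data: with 0, 30 and 80% of 8562 regions planted as shared, it estimated -0.2, 30.7 and 79.5%. The list step, run on simulated lists of 30 genes among 59702, called 2 of 100 lists with no effect, 75 of 100 with a fold of 2 and 100 of 100 with a fold of 3. These simulated lists held protein coding genes hit at the rates of IP 2. A call there needed an unadjusted p under 0.05 in a single simulated library. The rule for the real lists is stricter and IP 1 has fewer genes hit, so these rates are not those of the calls reported here. Alternatives covered score thresholds, list length, merging, the distance that counts as shared, each replicate alone, the genes with the most regions, overlapping genes and the drawing of random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.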

Results

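Enhanced crosslinking and immunoprecipitation (eCLIP) maps where a protein touches RNA in living cells. Ultraviolet light ties the protein to the RNA it contacts, the protein is pulled down, and positions with an excess of crosslinked RNA ends are called from the sequenced fragments. The protein here was APOBEC3B, a cytidine deaminase best known for acting on cytosine in single-stranded DNA, carried with a Flag tag by T-47D cells, an established luminal breast cancer line that expresses the estrogen and progesterone receptors. Its expression was switched on with doxycycline at 1 µg/ml for 48 h, and the cells were irradiated at 254 nm. The labels give 2 immunoprecipitated libraries (IP 1 and IP 2) and 2 size-matched input libraries. The question, from the study's title, was which RNA sites APOBEC3B binds in these cells. A list of called positions was analysed for each immunoprecipitated library. No list of an input library was analysed here, so none of the values below is set against input background, and read depth is unknown because the lists carry scores and no counts. IP 1 held 8800 called stretches, which merged into 8562 binding regions, and IP 2 held 34998 stretches in 33768 regions, 3.94 times as many. Most stretches were a single nucleotide, 57.6% in IP 1 and 58.3% in IP 2.

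Regions of the shorter list recurred in the longer one almost position by position. Of the 8562 IP 1 regions, 7997 (93.4%, Wilson 95% interval 92.9 to 93.9) had an IP 2 region on the same strand within 20 nt, and 92.8% overlapped one. Positions redrawn at random within the same genes met an IP 2 region in 8.35% of cases at 20 nt, so the observed share was 11.2 times higher (one-sided permutation p = 0.00498, the smallest that 200 redraws can give). Positions redrawn within 500 nt of their own place, an alternative added after the data were seen, met one in 15.1% of cases. In the other direction 24.6% of IP 2 regions were found in IP 1 (95% interval 24.1 to 25.1), against 2.19% of redrawn positions. The recurring regions were the high scoring ones. With each list split by score into 4 classes of equal size, 66.8% of the top class and 3.35% of the lowest class of IP 2 recurred in IP 1, and the shares of IP 1 regions recurring in IP 2 ran from 86.5% in the lowest class to 99.2% in the top one. Each of the 7997 recurring regions was paired with the highest scoring IP 2 region within 20 nt, which lay at the same position for 77.1%. Scores of these pairs correlated across regions (Spearman's rho 0.720, where regions are not independent replicates), and no pair had exactly the same score.

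The genes that held regions were shared in the same way. IP 1 had regions in 2096 genes and IP 2 in 5407, and 2066 genes were in both, where independent lists of these sizes drawn from all 59702 annotated genes would share 190. Among protein coding genes alone 1828 were shared and 445 expected. Both backgrounds are too wide, since a gene has to be transcribed to be called and RNA levels were not used here. Of the 20 genes with the most regions in each list, 15 were the same. Across the 1328 genes with at least 5 regions in IP 2, region counts in the lists correlated with a Spearman's rho of 0.651, where genes are not independent replicates.

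A small number of genes took a large part of both lists. TRPS1, a GATA-type transcriptional repressor, held the most regions in each list, 628 in IP 1 (7.33% of its regions, 95% interval 6.80 to 7.91) and 1301 in IP 2 (3.85%, 3.65 to 4.06). PRLR, the prolactin receptor, held 407 and 800. VPS8, a subunit of the endosomal tethering complex CORVET, held 380 and 723, and STK24, a serine/threonine kinase of the germinal centre kinase family, held 353 and 669. MED13L, a subunit of the kinase module of Mediator, followed with 204 and 634, PGR, the progesterone receptor, with 171 and 355, PHACTR1, a regulator of actin and protein phosphatase 1, with 117 and 436, and ESR1, estrogen receptor alpha, with 95 and 362. These 8 genes each held at least 1% of the regions of both lists. NCAM2, a neural cell adhesion molecule, passed 1% in IP 2 alone (77 and 360 regions) and NEAT1, the lncRNA scaffold of paraspeckles, in IP 1 alone (95 and 147).

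The other genes among the 20 with the most regions were THSD4 (52 in IP 1 and 280 in IP 2), GSE1 (70 and 196), LURAP1L (72 and 177), SATB1, a chromatin organiser (55 and 221), FARP1 (66 and 129), GREB1, an early estrogen response gene (57 and 144), NFIB, a nuclear factor I transcription factor (44 and 195), GRHL2, a transcription factor of epithelial cells (43 and 168), KCNK2, a potassium channel (45 and 119), and MALAT1, a lncRNA of nuclear speckles (57 and 71). Together the 20 genes held 36.1% of IP 1 regions and 22.2% of IP 2 regions. Inside TRPS1 the regions were spread over nearly the whole span: 223 of its 261 bins of 1 kb held a region in IP 1 and 254 in IP 2. Shares of single genes differed between the lists. TRPS1, PRLR, VPS8 and STK24 had 1.90, 2.01, 2.07 and 2.08 times the share in IP 1, and MALAT1 3.17 and NEAT1 2.55 times. In a comparison added after the data were seen, IP 2 was shortened to the length of IP 1 by score. The ratios were then 0.921, 0.933, 0.964 and 0.889, with 0.864 for MALAT1 and 0.792 for NEAT1. The larger shares in IP 1 were thus not found against the highest scoring IP 2 regions. Shortening by score changes the scores kept as well as the length, so an effect of length alone was not tested.

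**Figure D1:**
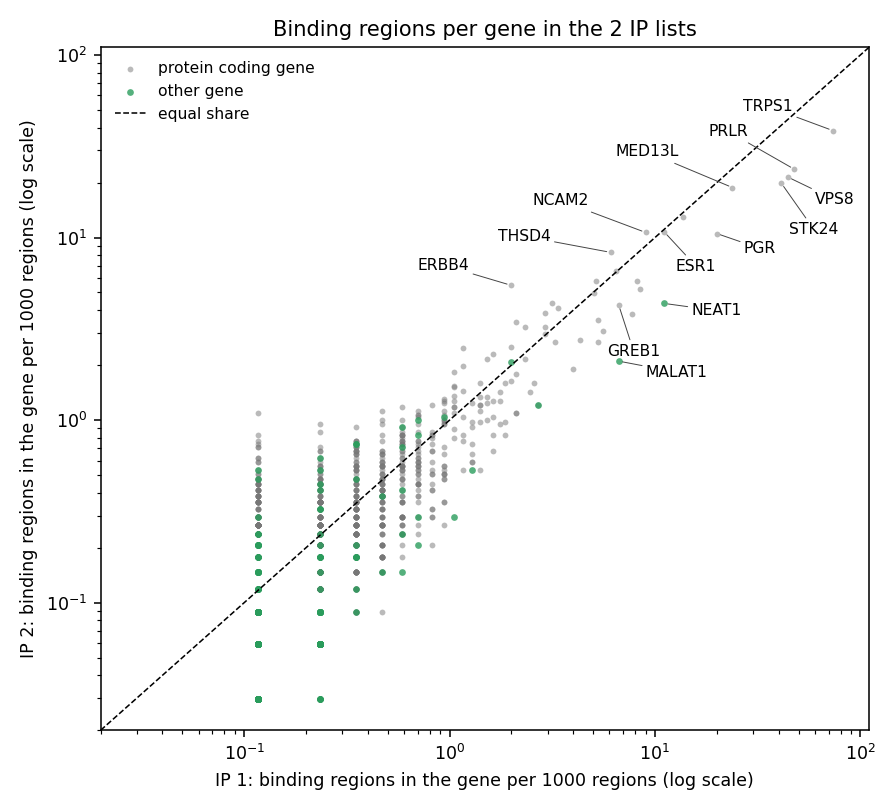
Binding regions per gene for the genes with a region in both lists, per 1000 regions of the list, IP 1 on the horizontal and IP 2 on the vertical axis, both on a log scale, with protein coding genes in grey and other genes in green. The dashed line marks an equal share in both lists; TRPS1 lies at 73.3 and 38.5 per 1000 regions and MALAT1 at 6.66 and 2.10, below the line, and ERBB4, chosen after its values were seen, above it at 1.99 and 5.48.

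By coordinates on GRCh38, TRPS1 spans chromosome 8 from 115408496 to 115668975, PRLR chromosome 5 from 35048756 to 35230487, VPS8 chromosome 3 from 184812166 to 185052614, STK24 chromosome 13 from 98445185 to 98577107, PGR chromosome 11 from 101029624 to 101129813, and ESR1 chromosome 6 from 151656672 to 152129619. Chromosome 3 held the largest share of regions, 10.7% ± 1.01 (SD, n = 2), followed by chromosome 8 with 9.53% ± 1.83 and chromosome 11 with 9.38% ± 1.36. Chromosome 1 held 7.26% ± 1.22.

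Almost all regions lay inside annotated genes, and most of those genes code for protein. Regions inside a gene made up 92.9% of IP 1 and 92.7% of IP 2, a mean of 92.8% ± 0.174 (SD, n = 2). Protein coding genes held 86.7% ± 0.776 of regions, lncRNA genes 4.05% ± 0.269, pseudogenes 1.07% ± 0.0891 and small RNA genes 0.912% ± 0.594. Of 20050 protein coding genes, 9.23% had a region in IP 1 and 24.0% in IP 2. Genes hit were long, with a median span of 40.5 kb in IP 1 and 40.9 kb in IP 2 against 24.1 kb for all protein coding genes, and 66 genes held 50% of the genic regions of IP 1 against 270 in IP 2. Whether a region lay in an exon or an intron was not analysed here.

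Small RNA genes took a larger share of IP 1 (1.33%, 95% interval 1.11 to 1.60) than of IP 2 (0.492%, 0.422 to 0.572; Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 4.56e-14 over 9 shares). Genes spanning over 100 kb also differed, with 48.6% of IP 1 and 44.5% of IP 2 regions (Fisher's exact test, adjusted p = 7.39e-11), and protein coding genes with 86.2% and 87.3% (adjusted p = 0.0216). The share inside genes did not differ past the threshold (exact test, adjusted p = 0.569). With IP 2 shortened to the length of IP 1 by score, the differences were not found: small RNA genes held 1.41% of its regions (Fisher's exact test against IP 1, adjusted p = 1), genes over 100 kb 48.6% (adjusted p = 1) and protein coding genes 85.5% (adjusted p = 0.951). Such tests compare these 2 libraries and no conditions. They count regions as independent, though many lie in the same gene and most IP 1 regions recur in IP 2. Their p-values therefore do not measure the spread between libraries. Shortening by score also keeps the highest scoring regions, so an effect of list length alone was not tested. Where regions at overlapping genes were given to the protein coding gene or lncRNA first, the small RNA share fell to 0.0631%.

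Genes that mark luminal, hormone-responsive breast epithelium held far more regions than their number would give. Of 31 luminal and estrogen response genes, 23 had a region in IP 1 and 25 in IP 2, which was 7.84 and 3.28 times the number in random lists matched on gene class and span (two-sided permutation test over random lists, Benjamini-Hochberg adjusted p = 0.0004 and 0.000444, from the smallest p that 10000 random lists can give). They held 10.7% of all IP 1 regions and 6.34% of IP 2 regions, 73.1 and 44.0 times the random lists. PRLR, PGR, ESR1 and GREB1 led the list, and the first 3 of these held 673 of its 917 regions in IP 1 and 1517 of 2141 in IP 2. Without those 3, a setting added after the data were seen, the folds by members hit were 7.84 and 3.30 and the folds by regions held fell to 28.1 and 17.8 (permutation p = 0.00640 and 0.00840, not adjusted). Members named after their values were seen include GATA3, a transcription factor of luminal cells, which held 37 and 93 regions, CA12, an estrogen-induced carbonic anhydrase, 28 and 90, and XBP1, a transcription factor of the unfolded protein response, 16 and 33. TFF1, TFF3, MYB, ERBB2 and SLC39A6, also on the list, held none. The call also held when random lists were drawn only from genes with a region and compared by the regions they held, a fold of 18.0. It fell to 5.60 without the 3 genes (permutation p = 0.0406 in IP 1 and 0.0512 in IP 2, not adjusted). These random lists were matched on gene class and not on span, so these 2 folds are not comparable to the span-matched ones above.

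Genes of RNA processing factors were also hit more often than random lists. Among 28 hnRNP genes, which code for nuclear proteins that coat new transcripts, 19 had a region in IP 1 and 26 in IP 2 (7.65 and 3.93 times the random lists). HNRNPA2B1 held 21 and 48 regions, HNRNPH1 8 and 22, and HNRNPA1 8 and 17. Among 30 genes of SR proteins and other splicing regulators, 21 and 25 had a region (7.42 and 3.34 times), led by TRA2B with 15 and 43 and RBM39 with 12 and 45, then the helicase gene DDX17 with 14 and 28, and TRA2A with 11 and 33. Many genes of both groups are known to make alternative transcripts with ultraconserved exons, and whether regions lay in those was not analysed here.

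Genes of the protein synthesis and folding machinery were hit more often than random lists too. Of 86 cytosolic ribosomal protein genes, 45 had a region in IP 1 and 65 in IP 2 (9.29 and 5.26 times), but with few regions each: RPL35A held 8 and 9, RPL37 5 and 19, RPS3 6 and 15, and RPS24 6 and 14. Of 30 translation factors, 13 and 24 had a region (4.81 and 3.30 times), among them PABPC1, the cytoplasmic poly(A) binding protein, with 12 and 18, EIF4A2 with 9 and 27, EIF4B with 4 and 22 and EIF2S3 with 3 and 11. Of 26 heat shock and chaperone genes, 12 and 21 had a region (5.35 and 3.56 times), with CANX, an endoplasmic reticulum chaperone, at 16 and 28, HSPA8 at 8 and 16, CALR at 7 in each list and PDIA3 at 4 and 13. Of 23 cytoskeleton and glycolysis genes, 8 and 12 had a region (5.35 and 3.03 times), among them TMSB4X with 5 and 8, ACTB with 5 and 6, ACTG1 with 2 and 6 and CFL1 with 2 in each. By the share of regions held, this last list did not pass (permutation test, adjusted p = 0.0564 and 0.106).

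By members hit, nuclear lncRNAs had the highest fold in IP 1 and snoRNA host genes in IP 2, while by regions held nuclear lncRNAs had the highest fold in both lists (407 and 170 times). Random lncRNA lists were almost empty, with 0.175 and 0.528 members hit and 0.472 and 2.16 regions held. For the luminal list 2.93 and 7.63 members were expected. The sizes of folds are therefore not comparable between lists of different gene classes. Of 15 nuclear lncRNA genes, 7 had a region in IP 1 and 9 in IP 2 (40.0 and 17.1 times the random lists), and they held 2.24% and 1.09% of all regions. After NEAT1 and MALAT1 came PVT1, a lncRNA next to MYC, with 17 and 70 regions, and NORAD, which binds Pumilio proteins, with 11 and 18. Of 18 host genes of snoRNAs, 5 and 9 had a region (31.3 and 21.1 times): ZFAS1 held 5 and 24, SNHG1 6 and 7, GAS5 5 in each list and TAF1D 3 and 8. KCNQ1OT1, MEG3, MIAT, JPX, CCAT1 and HOTAIRM1 were given no region in either list. Where a lncRNA overlaps a protein coding gene, regions went to the protein coding gene, and gene strands were not used. A lncRNA lying wholly inside a protein coding gene could therefore be given no region, so its count cannot tell whether it was bound.

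In all 10 of these lists, snoRNAs included, the adjusted p was under 0.05 in both libraries. The matching did not include RNA abundance, so the folds were not separated from differences in RNA level. With random lists drawn only from genes with a region and compared by regions held, 9 of the 10 calls ended, among them SR proteins (fold 2.75) and nuclear lncRNAs (fold 12.7). The folds of the ribosomal protein genes (0.855) and of the cytoskeleton and glycolysis genes (0.716) fell below 1. Matching on span was dropped in that setting too, so the effects of the pool, the measure and the matching were not separated.

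**Figure D2:**
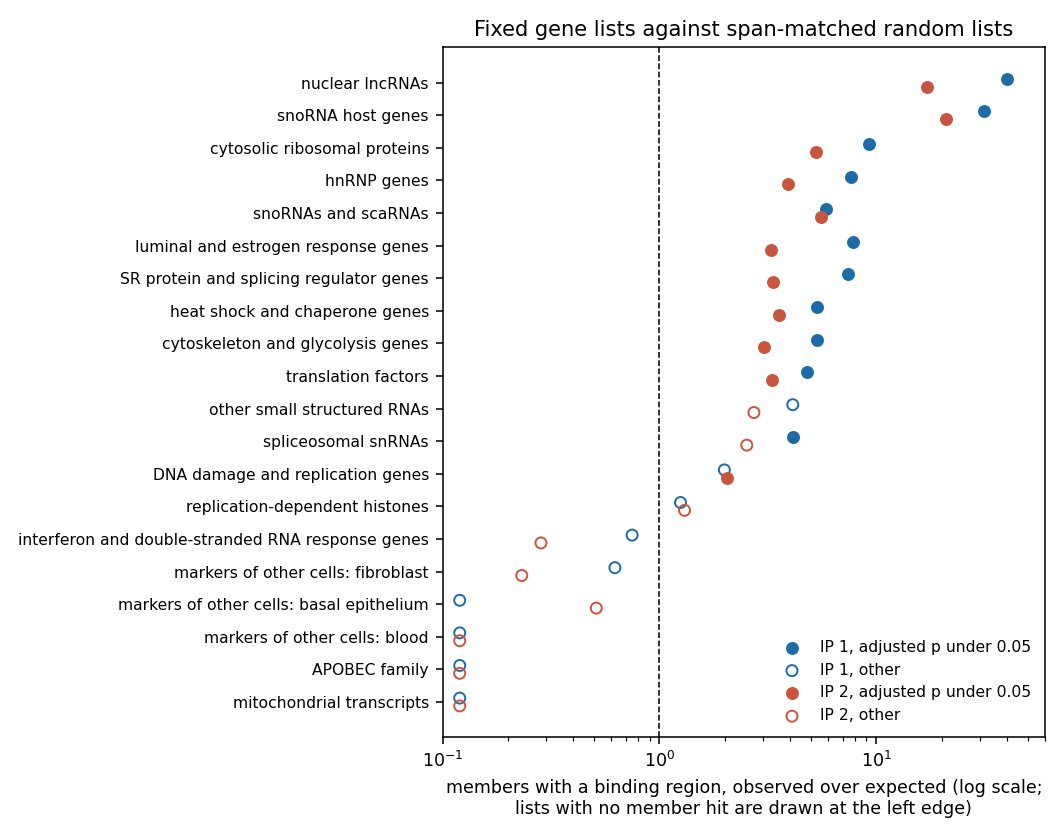
Number of members with a binding region over the number in 10000 random lists matched on gene class and span, for the 20 gene lists, with IP 1 in blue and IP 2 in red on a log axis. Filled points have a Benjamini-Hochberg adjusted p under 0.05; nuclear lncRNAs lie highest in IP 1 (40.0) and snoRNA host genes in IP 2 (21.1), and lists with no member hit are drawn at the left edge.

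Small nucleolar RNAs, which guide chemical modification of ribosomal and spliceosomal RNA, held some of the highest scoring positions. Of 573 snoRNAs and scaRNAs, 72 had a region in IP 1 and 91 in IP 2 (5.86 and 5.57 times the random lists, permutation adjusted p = 0.0004 and 0.000444), and 71 had one in both. SNORD104, SNORD144, SNORD19C and SNORD36B held 2 regions in IP 1 and 3 in IP 2 each. This call rests on giving a region at overlapping genes to the small RNA, and with the host gene placed first the fold was 0.278. The spliceosomal snRNA list was taken by symbol and pools gene copies with pseudogenes. Of its 1690 members, 5 and 7 were hit, with 1.21 and 2.77 expected (4.12 and 2.53 times). It passed the permutation test in IP 1 (adjusted p = 0.0280) and not in IP 2 (adjusted p = 0.0729). With random lists not matched on span its mean fold was 0.542. RNU6-2 and RNU6-9, copies of U6, held 2 regions in each list, RNU6-1 1 and 2, and RNU11, the U11 snRNA, 1 and 1. Of 15 other small structured RNAs RN7SK, the 7SK RNA, was hit once in each list (4.12 and 2.73 times, permutation adjusted p = 0.621 and 0.620).

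The top scoring position of both lists was the same nucleotide of RNU6-2, at position 1021553 of chromosome 19, with the authors' score at 229 in IP 1 and 218 in IP 2. A position of SNORD79 on chromosome 1 (173865410, score 197 in IP 1) and several of MALAT1 around 65499777 on chromosome 11 (scores 193 and 171) were also among the 10 highest scoring regions found in both lists. The copies of U6 are nearly identical to each other, so which copy is named at such a position is uncertain.

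Other lists were not enriched in both libraries. Among 30 DNA damage and replication genes, 6 had a region in IP 1 (1.99 times, permutation adjusted p = 0.237) and 17 in IP 2 (2.05 times, adjusted p = 0.00182), with MDM2 at 3 and 22 regions, TOP2A at 4 and 17, XRCC5 at 4 and 14 and ATR at 2 and 6. Among 69 replication-dependent histone genes, whose mRNAs end in a stem-loop and carry no poly(A) tail, 2 and 6 had a region (1.25 and 1.31 times, permutation adjusted p = 1 and 0.620). H2BC4 held 3 and 9, H2BC5 1 and 3, H4C15 0 and 4, and H2BC12 0 and 2. Among 29 interferon and double-stranded RNA response genes, 2 had a region in each list (0.748 and 0.284 times, permutation adjusted p = 1 and 0.0540): ADAR, an adenosine deaminase of double-stranded RNA, with 2 and 6, and BST2 with 1 and 5. None of the 37 mitochondrial transcripts was hit, and the whole mitochondrial genome held 0 regions in each list. With 1.28 and 2.09 members expected a 0 could not pass the test, and whether reads of that genome were kept before calling is not known here.

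No region lay in APOBEC3B itself at chromosome 22, 38982347 to 38992779, nor in any of the 11 genes of the APOBEC family (permutation adjusted p = 1 and 0.283). The tagged transgene's RNA has no place of its own on the genome, no count of its reads was used here, and whether reads of its coding sequence were left out before calling is not known, so the 0 leaves binding to that RNA undecided. Markers of other cell types were nearly free of regions. Of 15 fibroblast markers, COL6A3 alone was hit, with 1 and 2 regions (0.623 and 0.232 times, permutation adjusted p = 1 and 0.116). Of 15 markers of basal epithelium, EGFR and ITGA6 each held 1 region in IP 2 and none in IP 1 (0 and 0.511 times, permutation adjusted p = 0.599 and 0.449). None of 16 blood cell markers was hit (permutation adjusted p = 0.940 and 0.161). For the blood cell markers and the APOBEC genes too few members were expected for a 0 to pass.

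Regions gathered near the downstream ends of genes and not near their starts. The direction of each gene was taken from the strand of its regions, since gene strands were not used here. Within 1000 nt of the downstream end lay 9.27% of IP 1 regions and 8.56% of IP 2 regions, 2.80 and 2.69 times the share of positions redrawn in the same genes (permutation p = 0.00995 in each, the smallest that 200 two-sided redraws can give). Within 1000 nt of the gene start lay 3.20% and 3.15%, 0.960 and 0.993 times the redrawn positions (permutation p = 0.498 and 0.806). With the span cut into 10 equal parts, the last part held 18.6% of regions in IP 1 and 18.0% in IP 2. In genes up to 100 kb the last part held 26.7% and 24.3%, and in genes over 100 kb 11.6% and 11.4%, near the 12.9% and 14.1% of the first part. With each gene given equal weight, the last part held 25.4% of IP 1 regions in genes up to 100 kb and a near equal share in IP 2, and 13.3% and 15.4% in longer ones, where the first part held 19.1% and 15.1%. The difference between long and short genes was not tested. The distance to the gene end was chosen after the data were seen.

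In some long genes the regions filled some parts and left others nearly empty, and in others they were spread more evenly. The 3 equal parts of STK24 held 27.8, 37.1 and 35.1% of its IP 1 regions, and those of TRPS1 23.4, 47.5 and 29.1%. In NCAM2, 90.9% of IP 1 and 91.4% of IP 2 regions lay in the first of 3 equal parts of the span, and in PHACTR1 85.5% and 81.0%. In VPS8 the first 3 of 10 equal parts held 0.526% and 2.21% of regions, and in ESR1 the first of 3 parts held 8.42% and 7.22%. No region of GSE1, NFIB or KCNK2 lay in the first of 3 parts on the gene's main strand in either list, and 0.694% of GREB1 regions did in IP 2 and none in IP 1. In MED13L the first of 3 parts held 58.8% and 50.5%.

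**Figure D3:**
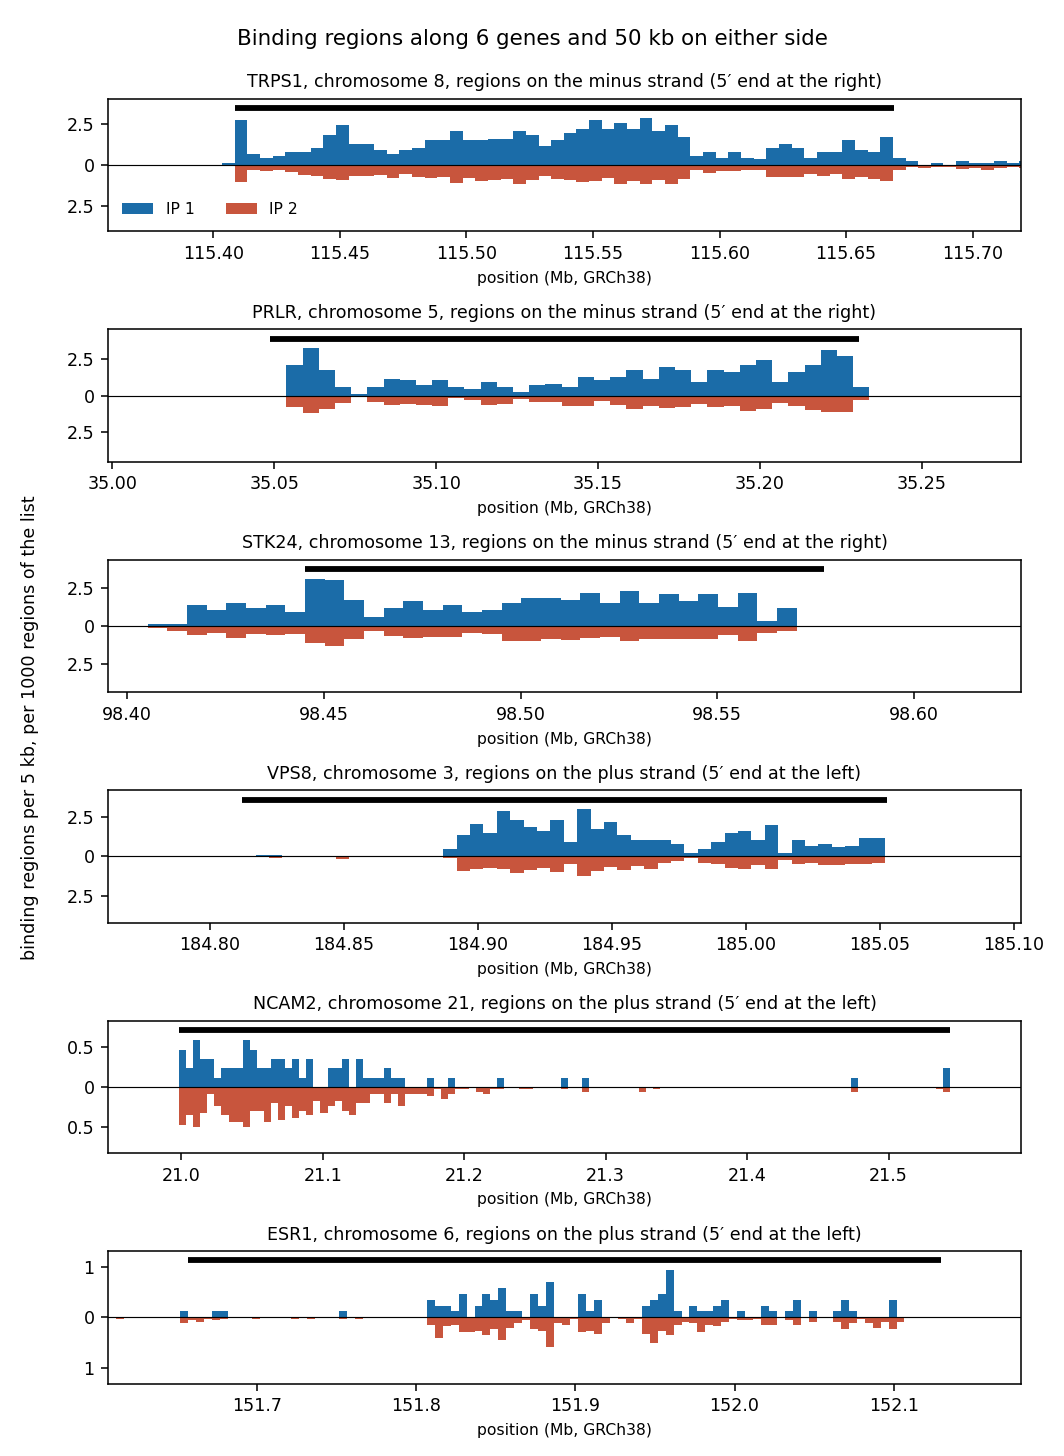
Binding regions per 5 kb along 6 genes with 50 kb on either side, per 1000 regions of the list, on the strand that carries the gene's regions, with IP 1 upward in blue, IP 2 downward in red and the annotated span as a black bar. NCAM2 regions lie mostly in the first of 3 equal parts of the span (90.9% in IP 1), VPS8 regions are sparse in the first 3 of 10 parts, and STK24 regions run on past its downstream end at the left.

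Regions of a gene lay almost without exception on one strand. Of the regions in genes with at least 5, 99.8% in IP 1 and 99.5% in IP 2 were on the strand that held most of the gene's regions, and in 239 of 239 genes with at least 5 regions in both lists that strand was the same. In IP 1, 234 of 239 genes had all regions on one strand, and in IP 2 1271 of 1328. STK24 is the case with the longest run past a gene end among the 20 genes with the most regions: 66 IP 1 and 129 IP 2 regions lay within 50 kb after its end on its own strand, reaching 36.9 kb, and none on the opposite strand. They are the same regions as those counted for FARP1, all on the minus strand between 98408292 and 98445085 of chromosome 13, so the count of FARP1 is uncertain. PRLR had no region within 50 kb of either end. TRPS1 had 12 and 50 before its start and 1 and 2 after its end. The strand and flank counts were chosen after the data were seen.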

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

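The tests of regions past gene ends and of the luminal genes without PRLR, PGR and ESR1 were chosen after their results, or part of them, had been seen. Contigs outside the assembled chromosomes, which no comparison uses, held 22 regions in IP 1 and 84 in IP 2, above 3, the upper limit that a count of 0 allows. That limit was applied after the counts were known, and no test set these regions apart. They made up 0.257% and 0.249% of the lists, with no control list to set them against.

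The luminal and estrogen response genes held 10.7% and 6.34% of regions. Ribosomal protein mRNAs are among the most abundant of a growing cell. With abundance of mature mRNA as the whole cause, their genes were predicted to have at least as many regions per kb of span. The density of ribosomal protein genes was lower, 0.342 times that of the luminal genes as a mean of both lists. It was 0.323 in IP 1 (95% bootstrap interval over members 0.154 to 0.957) and 0.361 in IP 2 (0.193 to 0.832). The low ratio rests on 3 genes: without PRLR, PGR and ESR1 it was 0.697, with intervals up to 1.54 and 1.48. Called regions per kb of span need not grow in proportion to mRNA abundance, and the exon part of each span was not used here. Regions where a small RNA overlaps a ribosomal protein gene also went to the small RNA. The ratio therefore does not decide, and abundance and any other cause cannot be told apart. RNA levels, unspliced transcripts included, were not used here, so a high output of these genes' precursor RNA stays open, and no biological explanation was tested.

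STK24 regions ran on past the gene's annotated end, but these 66 and 129 regions lie within FARP1 and add nothing to the counts below, which use only regions outside every annotated gene. Background without strand preference would put as many regions on the opposite strand. The genes used were protein coding, with at least 10 regions and at least 95% of these on one strand. After their ends the ratio of opposite-strand to same-strand regions was 0.0433 as a mean of both lists (0 opposite against 8 same-strand regions in IP 1, and 0.0867 in IP 2, 95% bootstrap interval 0.0174 to 0.229). This argues against such background for these genes only, since the filter favours genes with few opposite-strand regions. The IP 1 part rests on few regions. Transcription past the end predicts more regions after the end than before the start. Counts were equal in 65 of 74 genes in IP 1 and 437 of 487 in IP 2, and among the others the share of genes with more after the end was 0.552 as a mean of both lists, 33 against 17 genes in IP 2 (exact sign test p = 0.0328) and 4 against 5 in IP 1 (p = 1). Counted by regions the direction was the other one, 150 after the end against 215 before the start in IP 2 and 8 against 17 in IP 1, so this explanation stays open.

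IP 2 was 3.94 times as long as IP 1. A difference in depth or calling sensitivity predicts that regions found only in the longer list score lower, and their median score was 0.206 times that of the IP 2 regions recurring in IP 1 (2.34 against 11.4). Regions that do not recur also scored lower in the shorter list, with a ratio of 0.304 (1.20 against 3.95), so the test does not decide. Of the 7997 recurring IP 1 regions, 93.9% scored lower than the highest scoring IP 2 region within 20 nt. That goes with depth or sensitivity, but taking the highest of the nearby IP 2 regions can raise this share. Scores were not scaled between lists and read depth is unknown, so these and other differences between the libraries cannot be told apart. No design group separates the lists, so no biological explanation was tested.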

How the results depend on the processing

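Alternatives that gave small RNAs the last place, left out genes overlapping another protein coding gene, redrew positions within 500 nt, or left out PRLR, PGR and ESR1 were chosen after the data were seen, as were the strand and gene end results. The overlap of the lists, the strand shares and the gene end fold kept their direction and side of the threshold under every alternative run; the overlap was 66.2% with IP 2 shortened to the length of IP 1 and otherwise 92.6 to 97.9%, apart from 24.6% for IP 2 regions found in IP 1. The gene end fold ranged from 2.18 to 3.06 and the gene start fold from 0.953 to 1.11. Of the values of the 10 called lists, 109 of 120 kept their call, and of the 10 others 111 of 117 stayed uncalled. Sizes moved more than calls: in the top score class of 4 mean folds rose for luminal genes (5.56 to 16.9), SR proteins (5.38 to 12.6), chaperones (4.46 to 12.1), hnRNPs (5.79 to 11.1), ribosomal proteins (7.28 to 13.6), nuclear lncRNAs (28.5 to 71.5) and snoRNA hosts (26.2 to 55.7), and without matching on span ribosomal proteins fell to 4.40. In another setting, random lists were drawn only from genes with a region, were not matched on span and were compared by regions. There the call was lost for SR proteins (2.75), chaperones (1.42), hnRNPs (1.90), nuclear lncRNAs (12.7), snoRNA hosts (1.55), snoRNAs (1.05) and translation factors (1.10). The fold fell below 1 for cytoskeleton and glycolysis genes (0.716) and ribosomal proteins (0.855). This setting asks about regions per gene hit, not about genes hit. SnoRNAs fell to 0.278 with small RNAs last, which hands their regions to the host genes. Cytoskeleton and glycolysis genes lost their call in the top score class of 4 (5.73), where fewer genes are hit. DNA damage genes passed at or above the median score (2.84) and in IP 2 alone (1.99 to 2.05 over single lists), and snRNAs in the top score class (5.84), with IP 2 shortened (4.04), with stretches merged over 50 nt (3.53) and in IP 1 alone (2.53 to 4.12); the cause was not tested. The snRNA fold fell below 1, to 0.542, with random lists not matched on span, and was 1.03 among genes with a region by regions, neither called. By construction, score limits cut IP 1 to 4281 and 2141 regions, IP 2 to 16884, 8442 and 8562, and shared genes to 1092 at the median score and 559 in the top score class, with 856 when 2 regions were required. The chromosome 3 share was 12.3% in the top score class. The share inside genes was 93.0% in the top score class and with IP 2 shortened, 90.5% without the 10 genes with the most regions and 91.1% without overlapping genes. Protein coding shares were 85.3% (median score), 83.2% (top score class), 85.9% (IP 2 shortened), 83.4% (without the 10 genes) and 83.6% (without overlapping genes). In the same order lncRNA shares were 4.89, 6.25, 4.63, 4.33 and 5.02%, and 4.34% with small RNAs last; small RNA shares were 1.59% and 2.37% under the score limits and 0.0631% when last. Of 675 values of the 75 named genes, 178 moved by more than the spread of the lists and 497 did not. The values of each replicate alone could not move by this measure, so they are among the 497 by construction. No paired analysis was possible because the input libraries had no list here and no test compares groups. Not run, for want of sequence, exons or gene strands here, were the alternatives on UTR and transcript priority, annotation source, mRNA position, control positions, windows and k-mer length. The unknown read depth limits every statement on genes with few or no regions.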

Other observations

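All genes in this paragraph were chosen after their values were seen. Below the 20 genes with the most regions came further genes of epithelial identity and growth control: PARD6B, a cell polarity protein, with 48 regions in IP 1 and 104 in IP 2, CLDN1, a tight junction claudin, with 45 and 90, CADM1, an adhesion molecule, with 29 and 139, STC2, a secreted glycoprotein induced by estrogen, with 34 and 64, and TFRC, the transferrin receptor, with 23 and 41. Among the 76 protein coding genes with at least 10 regions in each list, XBP1 had the most per kb of span as a mean of both lists, 2.66 in IP 1 and 5.49 in IP 2, followed by CLDN1 with 2.69 and 5.38, STK24 with 2.68 and 5.07 and TRPS1 with 2.41 and 4.99, and further down by HNRNPA2B1 with 1.94 and 4.44 and KRT19, a luminal keratin, with 2.13 and 3.84. ERBB4, a receptor tyrosine kinase gene of 1163 kb, held 17 regions in IP 1 and 185 in IP 2, 0.362 times the share in IP 1, the lowest ratio of 42 genes with at least 60 IP 2 regions. With IP 2 shortened to the length of IP 1 by score the ratio was 0.680 and MPP7 had the lowest, 0.526. ERBB4 thus did not stand apart against the highest scoring IP 2 regions.

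In the snoRNA host genes GAS5 and SNHG1, chosen for this count after the data were seen, regions lay on the snoRNAs inside the host more than on the rest. In GAS5, 10 of 15 IP 1 regions and 13 of 19 IP 2 regions in the span fell in snoRNAs, which cover 15.6% of it, and in SNHG1 10 of 16 and 9 of 16, with 19.0% covered. ZFAS1 had 2 of 7 and 3 of 27 regions in snoRNAs with 2.45% covered, TAF1D 3 of 6 and 4 of 12 with 8.20%, and SNHG3 none of 5 and none of 8 with 8.32%. Nuclear copies of mitochondrial genes held 32 regions in IP 1 and 51 in IP 2, in 13 and 20 of 487 copies, with a median score of 20.5 and 17.5 against 3.54 and 3.29 for all regions. MTRNR2L12 held 9 and 10 and MTRNR2L8 5 and 9. The mitochondrial genome itself had 0 regions in both lists. Across protein coding genes grouped by span, the density of regions was 17.4 per Mb in IP 1 and 62.0 in IP 2 for the shortest of 10 classes. It was highest at 26.1 and 84.2 in the next class (median span 4.61 kb), and 4.45 and 15.5 in the longest class. The share of genes hit was 1.80% in the shortest and 13.9% in the longest class in IP 1, and 5.39% and 30.9% in IP 2. In IP 2 it was highest, at 34.8%, in the class before the longest.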
